A study of Rattus norvegicus with 6 samples.

How the data were processed

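RNA was sequenced in 6 libraries of rat trophoblast stem cells, the self-renewing precursors of the placental trophoblast, on differentiation day 8. Per the labels, 3 libraries came from cells carrying a control shRNA and 3 from cells carrying an shRNA against Tfpi, which encodes tissue factor pathway inhibitor, and virus-transduced cells were selected with puromycin before differentiation. The labels conflict on the source. A free-text description on most samples tells of placental tissue dissected from pregnant rats, whereas the source name, the cell type label and the design text name cultured trophoblast stem cells. The cells were taken as the source. Library numbers 1 to 3 (control) and 4 to 6 (Tfpi shRNA) were taken from the sample titles. No number occurs in both groups, so no pairing was used. Nothing states that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

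The deposited table gives RPKM, reads scaled by transcript length and by the mapped reads of the library, for 33654 transcripts in each library, per the file headers. The submitters' processing notes name the genome build Rnor 5.0. The aligner, the counting program, the annotation and the use of strand are not given in the sources used here. Of the 26121 gene symbols in the table, 4437 begin with a contig prefix (AABR07) used in a later rat assembly, so the annotation behind the table was left open and no coordinates are given. The table also holds the authors' own comparison, per the file headers an EDGE test with tagwise dispersions, with a deposited p-value, fold change and adjusted p-values for each transcript. RPKM values of transcripts sharing a symbol were summed, for 5193 genes with more than 1 transcript. Of the symbols, 70.6% were found in a current gene table, which was used for names only.

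RPKM is not a count, so no count model was used for the main result. Within each transcript the RPKM values of the libraries were whole multiples of a common step, and for all 21780 transcripts above 0 (100%) whole reads were recovered within a tolerance of 1e-06 of a read, widened to 0.001 of a read for 45 of them. The recovered reads gave the depth of each library and an added limma-voom fit.

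Genes with at least 1 RPKM in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3, on log2(RPKM + 1), with empirical Bayes moderation and a mean trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. Tfpi was also given an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3 libraries. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the members of a list move on balance in one direction and does not compare them with other genes. A list needed 3 tested members, which left 23 of 28 lists. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

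The test, the filter, the alternatives, the lists and the rule for named genes were fixed before the data were examined. The rule took Tfpi, the 12 largest rises and the 12 largest falls past the threshold with groups that did not overlap, a symbol, and a mean of at least 5 RPKM in the higher group, then up to 4 members of each list with the smallest p-values. There were 20 process lists and 8 marker lists, holding 486 genes of which 454 were found in the table, 1 of them through a synonym. The process lists covered trophoblast stem state, the prolactin family, giant cells, spongiotrophoblast and glycogen cells, invasive trophoblast, syncytiotrophoblast, coagulation and fibrinolysis, steroid synthesis, cholesterol synthesis, hypoxia and glycolysis, angiogenic factors, extracellular matrix, interferon response, p53 targets, unfolded protein and amino acid stress, S phase, mitosis, keratins and junctions, actin and smooth muscle, and NF-kB. The marker lists covered stromal, endothelial, leukocyte, erythroid, endoderm and pluripotent cells, ribosomal proteins and nuclear RNAs.

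The alternatives chosen at that point were quantile normalization, rescaling each library to a common total, limma without the mean trend, robust moderation, no filter, a filter of 5 RPKM, pseudocounts of 0.1 and 0.01, a fold of at least 1.5, an estimated correlation for the lists, and leaving out each library in turn. Median-ratio scaling, limma-voom on recovered reads, removal of a trend with transcript length (lowess span 0.3), transcripts tested one by one, lists without Tfpi, the giant cell list with Bhlhe40 in place of Stra13, and counts at a fold of 1.5 under each setting were added after seeing the data. The fit was tested on simulated data with 9877 tested genes, where 50 genes were changed at each fold. It recovered 54% of genes changed by a fold of 1.25, 96% at 1.5, 100% at 2 and 98% at 4. In the same data 7 unchanged genes were called, 3.87% of the calls. The squared coefficient of variation between simulated libraries, beyond sampling noise, was preset at 0.001. It was not fitted to the real libraries. The real data had 3570 called genes, far more than were changed in the simulation. These shares therefore need not hold for the real data. Genes that share reads with close relatives, such as prolactin, Ceacam and cathepsin genes and ribosomal protein genes with pseudogenes, have uncertain values, as do overlapping and antisense genes.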

Results

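Gene expression was measured by RNA sequencing in 6 libraries of rat trophoblast stem cells on day 8 of differentiation, 3 with a control shRNA and 3 with a Tfpi shRNA. A free-text description of most samples tells of dissected placental tissue instead, and the cultured cells named by the other labels were taken as the source. The recovered depth was 19011495, 20459147 and 18987685 mapped reads for control libraries 1 to 3 and 17702229, 17259247 and 18366618 for Tfpi shRNA libraries 4 to 6. Between 14419 and 14555 genes had a value above 0 in a library. The 10 most abundant genes took 10.2% to 11.4% of summed RPKM. A chi-square statistic of read counts per degree of freedom was 2.27 to 5.55 between libraries of a group and 26.6 to 34.1 between groups, so no pair of libraries agreed within sampling noise. Means below are ± SD over n = 3 libraries, in RPKM.

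The first comparison asked how far the shRNA lowered its target. Tfpi, an inhibitor of the tissue factor pathway of coagulation, was at 3312 ± 197 in the controls and 107 ± 15.9 with the Tfpi shRNA, or 3.23% of the control mean. Its log2 fold change was -4.95 (SE 0.09, limma adjusted p = 2e-08), and the 3 libraries of each group did not overlap. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. Both listed Tfpi transcripts fell: Tfpi_1 from 3055 ± 190 to 80.1 ± 13.1 and Tfpi_2 from 257 ± 7.85 to 27.0 ± 3.00. In the authors' deposited table the fold changes of these transcripts were -37.9 and -9.44.

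**Figure D1:**
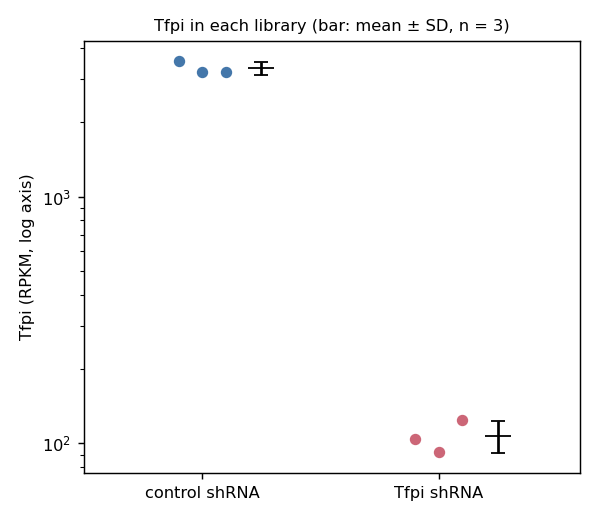
Tfpi expression (RPKM, log axis) in each control and Tfpi shRNA library; points are libraries and bars show the mean ± SD. The control libraries average 3312 and the Tfpi shRNA libraries 107.

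The second comparison asked which other genes differed between the groups. The largest rise among the named genes was that of Evpl, which encodes the cornified envelope protein envoplakin, from 3.79 ± 0.28 to 36.9 ± 2.81 (log2 fold change 2.98). The basement membrane collagen genes Col4a2 (1.78) and Col4a1 (1.67) followed, then Rbp7 (1.45), Abcc2 (1.40), the intermediate filament gene Des (1.39), Fgfbp1 (1.35), the protease inhibitor gene Serpine2 (1.24), Cd80 (1.18), Pxdn (1.16), Psca (1.14) and Med12l (1.11), as log2 fold changes. After Tfpi, the largest falls among the named genes were those of Rpl39l (-2.43), Ppp1r3b (-2.22), Pfpl (-2.12), Adm2 (-2.04) and Esam (-2.04). Crispld2 (-1.93), Glipr2 (-1.90), Plpp3 (-1.79), the glutathione peroxidase gene Gpx3 (-1.76), Impad1_1 (-1.74) and the prolactin family gene Prl7a3 (-1.72) came next. This order holds on the log2(RPKM + 1) scale. The ratio of RPKM means, Tfpi shRNA over control, was lower for Adm2 (0.099) than for Rpl39l (0.173). Prl7a3 fell from 1196 ± 38.0 to 364 ± 29.3 and Crispld2 from 219 ± 12.4 to 56.9 ± 4.51. Impad1_1 is uncertain, because it shares its name with a more abundant copy, 1 of its libraries was at 0 and its SE was 0.38. Its adjusted p was 0.0679 with robust moderation and 0.0875 with a pseudocount of 0.01.

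Of 9947 genes tested, 3570 (35.9%) passed an adjusted p of 0.05 in limma, 1520 higher and 2050 lower with the Tfpi shRNA. At a fold of at least 1.5 there were 142 higher and 282 lower genes, and at a fold of at least 2 there were 25 and 78. The groups did not overlap in 4930 genes (49.6%), against 10% by chance if the 6 libraries are independent. Nothing states that the libraries of a group came from separate cultures, so that share may not apply. The share of calls that were higher was 42.6% here, 53.3% after quantile normalization, 56.2% after rescaling to a common total and 51.7% with limma-voom on recovered reads, so the balance of small changes depended on scaling. The number of genes higher by a fold of 1.5 was 248 with a pseudocount of 0.1 and 272 after rescaling to a common total. The matching lower counts were 394 and 340.

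**Figure D2:**
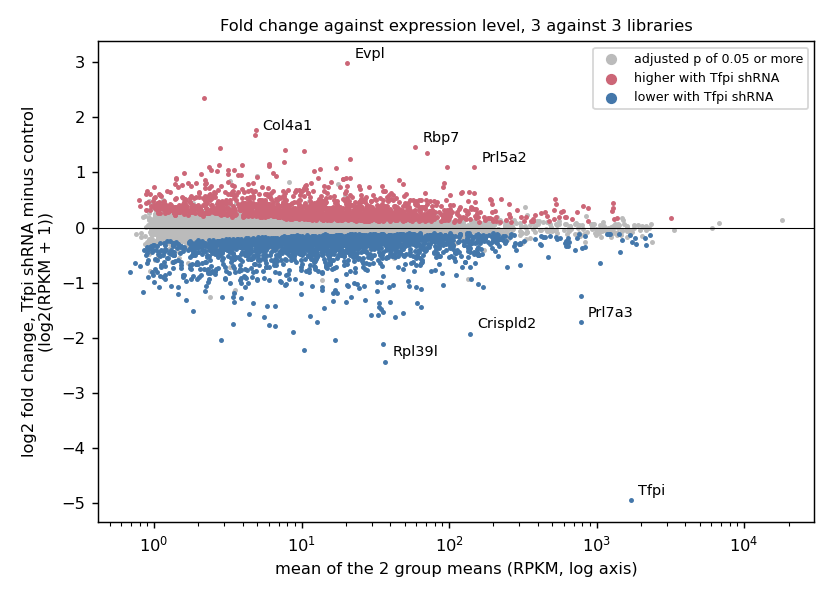
Log2 fold change (Tfpi shRNA minus control) against mean expression (RPKM, log axis) for the 9947 tested genes; each point is a gene, colored where it passed an adjusted p of 0.05. Tfpi lies apart at -4.95 and Evpl at 2.98.

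Among trophoblast genes, most tested members of the giant cell list fell. Of 14 tested members, 10 were lower, 2 were higher and 2 did not pass, and the counts adjusted over the list alone were the same (camera adjusted p = 0.0023; adjusted p = 0.27 with an estimated correlation). The transcription factor genes Fosl1 (81.9 ± 1.70 to 38.3 ± 2.40), Hand1 (70.3 ± 6.19 to 35.4 ± 4.76) and Gata3 (25.1 ± 1.07 to 17.5 ± 0.44) fell, as did the steroid enzyme gene Hsd3b1 (19.3 ± 1.57 to 8.22 ± 0.71). The 2 higher members, named after their values were seen, were Ctsj (0.79 ± 0.06 to 1.79 ± 0.21) and Stra13 (4.26 ± 0.17 to 5.32 ± 0.17), both with few reads. Stra13 did not pass with limma-voom on recovered reads (adjusted p = 0.252, within a range of 0.00168 to 0.252 over its alternatives). It is an older symbol of both Bhlhe40, the transcription factor meant by the list, and Cenpx, a centromere protein gene. Bhlhe40 has its own entry in the table and did not pass (43.0 ± 1.8 and 46.3 ± 1.6, limma adjusted p = 0.1038), and the Stra13 entry has an implied length of 201 bases, so its rise is not read as that of a giant cell gene. With Bhlhe40 in place of Stra13, a setting added after seeing the data, 1 member was higher, 10 were lower and 3 did not pass (camera adjusted p = 0.0014, within a range of 0.00032 to 0.0045 over its alternatives other than the estimated correlation). The giant cell lactogen gene Prl3b1, which was on the prolactin list, rose from 5.95 ± 0.81 to 10.3 ± 2.30 (limma adjusted p = 0.00458). Some other classic giant cell genes were listed under the filter and were not tested, and a listed 0 among them can be a failed estimate. Prl3b1 and these were also named after their values were seen. Prl3d4 was listed at 0 in all libraries but control library 2, where it was at 0.07, and Prl2c1 was at 0.45 ± 0.31 in the controls and 0.22 ± 0.12 with the Tfpi shRNA. The list members Ctsq (0.63 ± 0.13 and 0.97 ± 0.23) and Cts8 (0.17 ± 0.06 and 0.58 ± 0.16) had higher means with the Tfpi shRNA and Star (1.07 ± 0.36 and 0.63 ± 0.03) a lower one. The cathepsin gene Cts7, a tested list member, was lower with the length trend removed (log2 fold change -0.82, SE 0.18, limma adjusted p = 0.0081).

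In the steroid synthesis list, 7 of 10 members fell and none rose, also when adjusted over the list alone (camera adjusted p = 0.0022; adjusted p = 0.32 with an estimated correlation). Hsd17b2 went from 72.1 ± 1.02 to 34.2 ± 0.82, Cyp17a1, encoding the enzyme that leads to androgens, from 28.4 ± 0.54 to 13.2 ± 0.90, and Nr4a1 from 7.69 ± 0.73 to 4.76 ± 0.32. Hsd3b1 is on this list and the giant cell list. In the cholesterol synthesis list, 10 of 19 members fell and 2 rose, the same counts as over the list alone, and camera did not call it (adjusted p = 0.056; adjusted p = 0.62 with an estimated correlation). Fdps (log2 fold change -0.41), Hmgcs1 (-0.34), Msmo1 (-0.31) and Hmgcr (-0.24) were among those that fell. The list passed without control library 2 (adjusted p = 0.0377) and without Tfpi shRNA library 5 (adjusted p = 0.0342), and also with no filter, with limma-voom and with the length trend removed, within a range of 0.02 to 0.143 over its alternatives other than the estimated correlation.

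In the invasive trophoblast list, 13 of 21 members fell and 5 rose, with the same counts over the list alone (camera adjusted p = 0.0197; adjusted p = 0.61 with an estimated correlation). Tfpi is itself a member, and without it the adjusted p was 0.0588. Ceacam9 (log2 fold change -1.32) and Cited2 (309 ± 9.38 to 188 ± 8.26) fell. Fosl1, also on the giant cell list, and Cdh5, also on the endothelial marker list, are among the members that fell. The prolactin family had 2 higher and 4 lower members of 9, also over the list alone, and was not called (adjusted p = 0.63), with a median log2 fold change of 0.08 and a mean of -0.09. Prl7a3 fell while Prl5a2 rose from 93.8 ± 8.55 to 202 ± 29.0, and reads shared between these related genes leave their values uncertain. The stem state list had 1 higher and 5 lower members of 14 (adjusted p = 0.32), with Tfap2c (log2 fold change -0.30) and Lifr (-0.49) lower. Lifr is also on the giant cell list. The spongiotrophoblast and glycogen cell list had 3 higher and 7 lower of 13 (adjusted p = 0.37), with Plac8 at 1290 ± 50.9 against 824.5 ± 12.1 and Slc2a3 higher (log2 fold change 0.67). The syncytiotrophoblast list had 1 higher and 2 lower of 8 (adjusted p = 0.56), with Tfrc higher (0.49) and Ly6e lower (-0.25). Each of these 3 lists had the same counts adjusted over the list alone.

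In the coagulation and fibrinolysis list, 4 of 14 members rose and 6 fell, also over the list alone, and the list was not called (camera adjusted p = 0.57), with a median log2 fold change of 0.02 and a mean of -0.44. Without Tfpi, the mean of the other 13 members was -0.09, the median was 0.03 and the camera direction turned upward (adjusted p = 0.992). Besides Tfpi, the thrombomodulin gene Thbd, an anticoagulant receptor, fell from 44.7 ± 1.73 to 14.2 ± 0.67, and the protein C receptor gene Procr from 58.9 ± 0.91 to 40.7 ± 1.34. Serpine2, a thrombin inhibitor, rose from 12.4 ± 0.62 to 30.5 ± 1.40. The tissue factor gene F3, named after its values were seen, fell from 3.43 ± 0.11 to 0.998 ± 0.22.

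The extracellular matrix list rose, with 7 higher and 2 lower of 12 members and 9 and 2 when adjusted over the list alone (camera adjusted p = 0.0082; adjusted p = 0.61 with an estimated correlation). Col4a1 went from 1.79 ± 0.20 to 7.88 ± 0.48, Col4a2 from 1.68 ± 0.45 to 8.11 ± 0.56 and Loxl2 from 10.6 ± 0.54 to 15.7 ± 1.11, while Bgn fell from 8.22 ± 0.23 to 3.80 ± 0.54. The p53 target list had 8 higher and 3 lower of 16 members, 9 and 3 over the list alone (camera adjusted p = 0.0131; adjusted p = 0.27 with an estimated correlation). Mdm2, a negative regulator of p53, rose from 94.9 ± 3.15 to 149.7 ± 5.22 and the cell cycle inhibitor gene Cdkn1a from 28.2 ± 2.17 to 45.3 ± 5.35, while Btg2 fell from 178 ± 0.42 to 132 ± 5.97.

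The mitosis list had 8 higher and 1 lower of 24 members, 10 and 1 over the list alone (camera adjusted p = 0.0048; adjusted p = 0.68 with an estimated correlation). Its changes were small, such as Kif20a (log2 fold change 0.48), Kif23 (0.28) and Aurkb (0.20) higher and Mki67 (-0.24) lower. The S phase list had 8 higher and 3 lower of 24, 9 and 3 over the list alone, and was not called (adjusted p = 0.056; adjusted p = 0.68 with an estimated correlation), with Tyms (0.50), Mcm3 (0.39) and Mcm5 (0.33) higher and Mcm7 (-0.26) lower. It passed without control library 2 (adjusted p = 0.0261) and without Tfpi shRNA library 4 (adjusted p = 0.0289), and also with limma-voom and after quantile, common-total and median-ratio scaling, within a range of 0.0261 to 0.102 over its alternatives other than the estimated correlation. The interferon response list had 4 higher and 0 lower of 10 tested members, also over the list alone. Its camera adjusted p was 0.039, and 0.32 with an estimated correlation. Stat1 (0.56), Irf1 (0.39), Tap1 (0.36) and B2m (0.19) were higher. The list held 27 genes, and members such as Isg15, Ifit1, Mx1 and Irf7 were under the filter and not tested. It did not pass without Tfpi shRNA library 4 (adjusted p = 0.0549), with no filter or with limma-voom, within a range of 0.0266 to 0.0701 over its alternatives other than the estimated correlation.

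**Figure D3:**
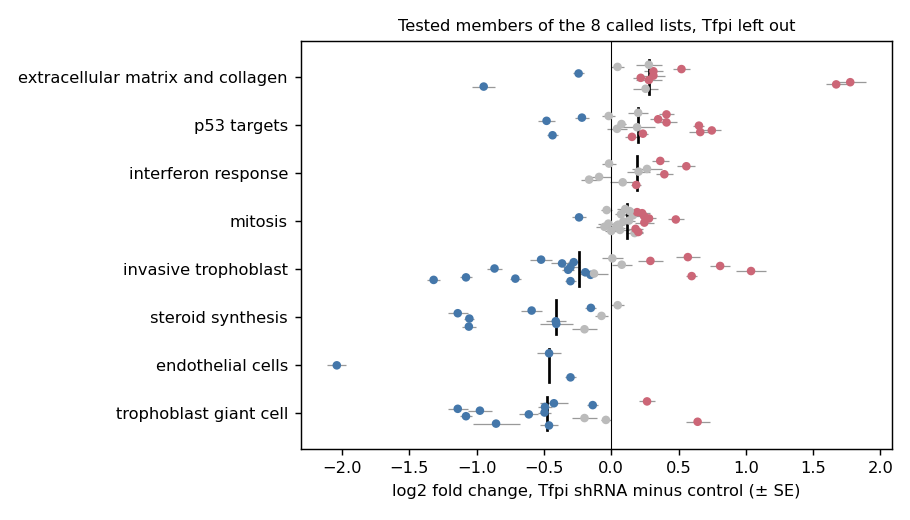
Log2 fold change (Tfpi shRNA minus control, ± SE) of the tested members of the 8 called lists without Tfpi; each point is a gene, gray where it did not pass an adjusted p of 0.05, and black bars are medians. Giant cell and steroid synthesis members lie mostly below 0, and Col4a1 and Col4a2 stand at 1.67 and 1.78.

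Of 56 markers of other cell types in the table, 16 were listed at 0 in all 6 libraries. Rpl8, a ribosomal protein gene that every cell uses, was also listed at 0 in all of them, so a 0 can be a failed estimate and those 16 were not counted as low. Of the markers above 0 in at least 1 library, all 4 erythroid and all 8 endoderm markers had means under 1 RPKM, as did 6 of 7 stromal, 6 of 8 leukocyte, 5 of 8 endothelial and 2 of 5 pluripotency markers. The stromal exception, Pdgfra, was 3.06 ± 0.17 in the controls and 2.30 ± 0.25 with the Tfpi shRNA (adjusted p = 0.019; 0.0684 without control library 1 and 0.0653 without Tfpi shRNA library 5). The 3 tested endothelial markers fell, also over the list alone (camera adjusted p = 0.0082; adjusted p = 0.27 with an estimated correlation; adjusted p = 0.103 with no filter, within a range of 0.0028 to 0.103 over the remaining alternatives). They were Cdh5 (209 ± 4.78 to 169 ± 7.29), Esam (27.9 ± 1.53 to 6.03 ± 0.58) and Tie1 (1.19 ± 0.12 to 0.59 ± 0.09). Cdh5 is also on the invasive trophoblast list and Tie1 on the angiogenic factor list. The endothelial markers Tek, Emcn and Erg had only 2, 1 and 17 reads over all libraries. The call is therefore not read as a fall in endothelial cells. Csf1r rose from 3.53 ± 0.32 to 6.16 ± 0.51, and Cd68 was at 2.10 ± 0.23 and 1.66 ± 0.48. Lin28a fell from 2.41 ± 0.16 to 0.48 ± 0.10 and Tdgf1 rose from 26.4 ± 2.88 to 32.7 ± 1.98, in a pluripotency list that was not called (adjusted p = 0.69). Of 15 tested ribosomal protein genes 1, Rpl10, passed (log2 fold change -0.11; lost under 10 of its alternatives), 0 over the list alone, and the list was not called (adjusted p = 0.56). Of the nuclear RNAs, Snhg11 rose (0.52) and Tug1 was at -0.11.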

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

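The median-ratio, voom, length, transcript, without-Tfpi and Bhlhe40 settings, and counts at a fold of 1.5 under other settings, were chosen after the data were seen. The log2 fold change of Tfpi lay between -5.06 and -4.85 when each library was left out. Called genes numbered 2726 to 3450 in the same fits, with 1106 to 1466 higher. With limma-voom on recovered reads the log2 fold change of Tfpi was -4.59, outside that range. No gene called in the main fit was called in the opposite direction under any of the other 17 gene-level settings listed. At a fold of at least 1.5 the called genes fell to 424, 142 higher and 282 lower, by construction. At that fold the higher and lower counts were 272 and 340 after rescaling to a common total. They were 248 and 394 with a pseudocount of 0.1, and 262 and 411 with 0.01. With limma-voom on recovered reads they were 289 and 391, and with a filter of 5 RPKM 87 and 184. Fewer genes were tested under the filter, and smaller pseudocounts raise the folds of low genes. The common total lay above the summed RPKM of each library (448700 to 473188), while the pseudocount and the filter stayed at 1. Rescaling therefore also acted as a smaller pseudocount and a lower filter, with 10840 genes tested. This was not separated from scaling between libraries. The cause of the move with limma-voom was not tested. Of 23 lists tested, camera called 8 with the preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05, and fry gave an adjusted p under 0.05 for 17. Of 1809 values of named genes under the alternatives, 24 lost the threshold, in Impad1_1, Slc16a3, Rpl10 and Pdgfra, 4 gained it and 0 reversed. The depth of 17259247 to 20459147 mapped reads limits statements on genes near 1 RPKM.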

Other observations

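Other lists fixed beforehand moved in both directions, and camera called none of those given here. In the hypoxia and glycolysis list 7 of 20 members rose and 3 fell (adjusted p = 0.18), with Pfkfb3 (14.5 ± 0.75 to 28.1 ± 0.60), Vegfa (30.8 ± 0.45 to 45.6 ± 2.29) and Ankrd37 (61.6 ± 3.53 to 86.1 ± 7.09) higher. In the angiogenic factor list 2 of 9 rose and 4 fell (adjusted p = 0.63), with Kdr higher (log2 fold change 1.04) and Efna1 (-0.49) and Adm (-0.46) lower. In the keratin and junction list 8 of 17 rose and 6 fell (adjusted p = 0.63), with a median log2 fold change of -0.06, a mean of 0.01 and a camera direction upward, and with Cldn4 at 13.6 ± 0.48 and 26.2 ± 0.73 and Krt7 at 143.7 ± 0.62 and 78.5 ± 6.97. The unfolded protein and amino acid stress list had 6 higher and 6 lower of 21 (adjusted p = 0.32), with Ddit3 (0.64), Hsp90b1 (0.29) and Hspa5 (0.29) higher and Phgdh (-0.72) lower. The actin list had 2 higher and 5 lower of 9 (adjusted p = 0.27), with Vcl (-0.37), Cnn2 (-0.32) and Actn1 (-0.23) lower and Smtn (0.30) higher. The NF-kB list had 1 higher and 3 lower of 6 (adjusted p = 0.24), with Relb (-0.75) and Nfkbiz (-0.23) lower and Tnfaip2 (0.25) higher. Adjusted over the list alone, the stress list had 7 higher and 6 lower and the NF-kB list 1 and 4, and the other 4 lists here had the counts given.

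A pair of genes outside the naming rule was picked after the values were seen. Ceacam15 fell from 1096 ± 48.5 to 463 ± 39.0. Grcc10 was listed at 0 in all 3 controls and at 2.22, 5.47 and 5.43 in Tfpi shRNA libraries 4 to 6. A listed 0 can be a failed estimate, as for Rpl8, so these values are not read as a gene switched on.

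All of the tests below were chosen after the results were seen. The authors' deposited table called 193 transcripts, 56 higher and 137 lower, whereas limma called 3193 of 11803 transcripts tested one by one. Of the 182 genes behind the deposited calls, 176 were called the same way in limma. A candidate explanation is that the deposited test read RPKM values as if they were counts. A binomial p on rounded RPKM sums differed from the deposited p by a median of -0.036 on the log10 scale over 3025 transcripts with a deposited p between 1e-20 and 0.5. A test on reads would not see transcript length among transcripts with alike read numbers. Among transcripts with 200 to 1600 reads per library and a fold of at least 2, split by length within 3 read classes, the deposited table called 32 of the 45 shorter and 7 of the 42 longer ones, whereas limma called 41 and 37. The two-sided permutation p was 2e-05, the smallest that 100000 permutations can give, which argues against a test on reads. The shorter and longer transcripts had median reads of 480 and 407 and median absolute log2 fold changes of 1.178 and 1.235 in reads. Of limma's calls with a fold of at least 2, the deposited table called 3 of 33 transcripts under 10 RPKM with at least 100 reads and 55 of 61 at 10 RPKM or more.

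The rise of extracellular matrix genes was weighed against a trend with transcript length and against stromal, visceral endoderm or parietal endoderm cells in the knockdown cultures. Across genes, which are not independent replicates, the fold change had a Spearman correlation of 0.106 with length. With the length trend removed, 6 of the 7 rising members stayed past the threshold, Col4a1 at 1.66 and Col4a2 at 1.77. Col5a1 went from 0.28 (SE 0.10) to 0.27 (SE 0.10) with an adjusted p of 0.0542, having lain close to the threshold before. Stromal cells would bring their abundant collagen transcripts, but Col1a1 (0.04 ± 0.01 to 0.03 ± 0.02) and Col3a1 (0.09 ± 0.04 to 0.09 ± 0.01) stayed low while the mean of Col4a1 rose by 6.09 RPKM. Among 7 stromal markers above 0 in at least 1 library, the highest rise was 0.203 RPKM, in Pdgfrb, which argues against stromal cells. Of 4 abundant stromal markers listed, only Col1a1 and Col3a1 were above 0, so the argument rests mainly on these. Visceral endoderm would bring abundant Apoa1 and Apoa2, but among 8 endoderm and yolk sac markers above 0 in at least 1 library the highest rise was 0.0843 RPKM, in Apoa1, which argues against it. Of 5 abundant endoderm markers listed, only Apoa1 and Apoa2 were above 0, with 4 and 3 reads over all libraries. The argument rests mainly on these. For parietal endoderm 3 abundant matrix transcripts were set against 10% of the rise of Col4a1. Lama1 went from 0.14 ± 0.03 to 0.36 ± 0.07. This is the direction such cells would bring, though the difference of 0.218 RPKM was under that bound. The means of Sparc (2.26 ± 0.37 and 2.94 ± 0.28) differed by 0.685 RPKM, slightly over the bound. Sparc did not pass the threshold in the main limma fit (adjusted p = 0.055) but passed with the length trend removed (adjusted p = 0.047). Lamb1 fell from 59.4 ± 1.02 to 50.1 ± 1.80, from a baseline that would hide a small share. Parietal endoderm therefore stays open, as the difference in Sparc was not under the bound. A response to lower Tfpi, an off-target effect of the shRNA and a change in trophoblast makeup stay open, as untested.

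The fall of most tested trophoblast giant cell genes was weighed against a lower share of giant cells alone and against scaling between the libraries. A lower share alone would raise markers of the other trophoblast types alike. The stem state, spongiotrophoblast and syncytiotrophoblast lists had 34 tested members that the giant cell list does not hold. Past the threshold, 5 of them rose and 13 fell. Among all 9947 tested genes, 1520 were higher and 2050 lower, so calls in both directions were common in any case. Whether giant cells also express these genes was not measured. The counts therefore cannot decide on a lower share alone. Under quantile, common-total and median-ratio scaling at least 9 of the 10 falling members stayed lower past the threshold, which argues against scaling. Limk2, with a small fold of -0.14 (SE 0.04), lost its call at -0.11 (SE 0.04) under quantile and -0.10 (SE 0.04) under common-total scaling. The list's median log2 fold change was -0.48, and -0.44 to -0.46 under those scalings, whereas the median of all genes moved only between -0.02 and 0.02. The giant cell lactogen gene Prl3b1 rose (5.95 ± 0.81 to 10.3 ± 2.30). Ctsq and Cts8, both near the floor, had higher means with the Tfpi shRNA. The cathepsin gene Cts7 went the other way (log2 fold change -0.82, SE 0.18, with the length trend removed). How far the list reflects giant cells is therefore open. A lower share alone stays open. A lower share together with changes within cells, an effect of lower Tfpi and an off-target effect also stay open, as untested.

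The count of 3570 called genes was set against other splits of the libraries. Of the 10 splits into 3 and 3, 1 gave as many genes, the real one, and the highest of the others called 1. With 10 splits the share cannot fall under 0.05. Each other split mixed control and Tfpi shRNA libraries, so the difference between the groups entered its spread and held down its calls. Those counts therefore do not measure how many genes would be called without a difference.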
